A study of Mus musculus with 14 samples.

How the data were processed

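Bulk RNA sequencing was made from small pools of sorted and cultured mouse epidermal cells with Smart-seq2 cDNA and Nextera XT libraries, per the labels' protocols; Smart-seq2 copies polyadenylated RNA from small amounts of material. The authors deposited 1 table of raw counts per gene symbol, whole numbers that were not normalised, for 14 libraries. Reads were aligned with HISAT2 to mm10/GRCm38 and counted with featureCounts, per the submitters' processing notes. Whether counting used strand, and how it treated reads that match several genes, is not given in the sources used here. Genes that overlap on opposite strands, paralogs and pseudogenes are therefore uncertain.

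The table holds 55228 symbols, of which 26607 had a count in at least 1 library. Groups were taken from the sample labels: 8 control and 6 distal libraries. The sample descriptions place them in 4 sets, which are nested in the regions, so no set holds both regions and no comparison of regions within a set could be made. Libraries of a set differed from each other by more than sampling noise in all 23 pairs (chi-square per degree of freedom 6.83 to 40.0 over genes with at least 10 counts in a pair), but without molecular identifiers this does not exclude that some are technical duplicates. They were kept as separate libraries, with counts summed per set as an alternative. Correlations of log2 CPM were 0.873 to 0.929 within sets and 0.782 to 0.897 between regions.

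Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM scaling, and the two-sided quasi-likelihood F test with robust estimation, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Log2 fold changes are distal minus control, and their SE is the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled totals. The median log2 fold change over all tested genes was -0.16 with TMM, -0.18 with the size factors of DESeq2 and 0.00 with upper-quartile scaling, and fold changes are to be read against that shift. No named gene changed direction between these 3 scalings. Sets of a region were compared in a model with 4 sets, which shares 1 estimate of the spread.

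Gene lists were fixed before the data were examined: 33 lists with 833 entries, of which 5 symbols were matched through synonyms and 3 were not found. The 28 lists with at least 5 tested members, without the sex-linked one, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists; an estimated correlation and fry were alternatives. Library measures were compared with exact permutation tests over all 3003 regroupings, adjusted over 4 measures. The named genes follow a rule fixed before the data were examined: the 12 largest rises and the 12 largest falls among genes past the threshold with average log2 CPM of at least 3, a proper gene name and both distal sets on the same side of both control sets; up to 4 members with the smallest p in each list described; and Lrig1, Ly6a, Ring1, Rnf2, Krt6a and Krt17. Exceptions are marked in the text.

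Gene positions, biotypes, and the median length and GC content of each gene's transcripts came from the GENCODE annotation of GRCm38; 99.1% of tested genes had a GC value. After the GC trend was seen, each library's deviation from the gene mean was fitted with natural splines (4 degrees of freedom each) of GC content and log2 length, and the fit was entered as edgeR offsets. Other alternatives chosen after seeing the data were libraries over 4000000 counts only (8 control and 2 distal), the total count as a covariate, and the GC removal on counts summed per set. Alternatives chosen before were other scalings, DESeq2 1.42.0, limma-voom, counts summed per set, other filters on low counts, covariates and blocks, thinned counts, and leaving out each set and each library.

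The code was tested on simulated counts with the real means, totals and dispersions of 11654 genes, 200 of them changed, for the distal against control comparison. It recovered 13.4% of genes changed 1.5-fold, 47.8% of those changed 2-fold and 84.8% of those changed 4-fold, and called 6 of 11454 unchanged genes. With an added GC trend of opposite sign in the 2 regions, 25.5% of unchanged genes were called before and 0.0175% after the trend was removed. That trend was linear in the same GC values that the removal uses, with the same slope in every library of a region. The simulation therefore does not show how fully a real trend is removed. Depth limits low genes most in the distal libraries, which have 2137934 to 4513518 counts; reads carry no molecular identifiers in the table, so counting error alone understates the error of a single library. Raw reads were not used here.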

Results

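Transcript counts were measured in cultured mouse epidermal cells that carried a fluorescent lineage label for Lrig1, a gene of upper hair follicle progenitors. The cells came from tail epidermis 8 weeks into the time course that the labels call pw1, were sorted for the surface antigen Sca1, and were then grown for 1 week in keratinocyte medium. They were taken from a control region outside the memory zone (8 libraries) or from a distal region that the study associates with memory of an injury (6 libraries). The libraries came from 4 sets, 2 in each region, with 6 and 2 control libraries and 2 and 4 distal libraries. No label says that libraries come from separate animals or cultures, so p-values over libraries measure only the spread between these libraries, which may be technical.

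Total counts ranged from 4515646 to 7458872 in the control libraries and from 2137934 to 4513518 in the distal libraries, so the regions did not overlap in depth. The means were 5917030 ± 931160 (SD, n = 8) and 3195365 ± 1052700 (SD, n = 6), with adjusted p = 0.00133 over 4 library measures in a two-sided exact permutation test. Genes with a count numbered 16986 ± 688 (SD) in control and 16016 ± 373 (SD) in distal libraries (exact permutation, adjusted p = 0.026), but with all libraries thinned to the smallest total the means were 15264 and 15423 (exact permutation, p = 0.57). Mitochondrially encoded genes took 5.39% ± 1.12 (SD) of control and 3.67% ± 1.57 (SD) of distal counts (exact permutation, adjusted p = 0.0488). That call was lost without control set 2 or distal set 1 (differences of -1.18 and -1.13, exact permutation p = 0.12 and 0.18). The 50 largest genes took 19.0% ± 1.46 (SD) and 19.4% ± 1.03 (SD), a difference that did not pass (exact permutation, adjusted p = 0.584). The noncoding transcript Gm26917, looked at after the data were seen, took 0.756% ± 0.240 (SD) of control and 1.81% ± 0.580 (SD) of distal counts (exact permutation, p = 0.00067). The Y-linked gene Ddx3y averaged 95.3 CPM ± 31.6 (SD) in control and 57.1 CPM ± 23.1 (SD) in distal libraries, and Xist averaged 7.19 CPM ± 6.91 (SD) and 3.14 CPM ± 3.33 (SD). Ddx3y had a log2 fold change of -0.74 (edgeR adjusted p = 0.037). The Y-linked genes Eif2s3y, Uty and Kdm5d were at -1.16, -0.99 and -0.90 (edgeR adjusted p = 0.00022, 0.014 and 0.052). With the GC trend described below removed, no tested sex-linked gene passed.

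The main question was how the transcriptome of distal cells differed from that of control cells once both had left the tissue. Krt17, a keratin of hair follicle and activated epidermis (chromosome 11, 100256217 to 100261029, GRCm38), rose from 3548 CPM ± 780 (SD, n = 8) to 10800 CPM ± 2214 (SD, n = 6) in distal cells. Its log2 fold change was 1.61 ± 0.17 (SE), with an edgeR adjusted p of 2.5e-06, and every distal library lay above every control library. Lrig1, whose lineage label defined the cells (chromosome 6, 94604529 to 94700158), rose from 43.9 CPM ± 9.31 (SD) to 79.1 CPM ± 10.4 (SD), a log2 fold change of 0.85 ± 0.17 (SE; edgeR adjusted p = 0.00046). Krt6a, a wound keratin, was at 3416 CPM ± 771 (SD) and 3913 CPM ± 530 (SD) and did not pass (edgeR adjusted p = 0.32). Ly6a, which encodes the Sca1 antigen, had a log2 fold change of -0.44 ± 0.18 (SE; edgeR adjusted p = 0.048). That call was lost with counts summed per set (log2 fold change -0.20, edgeR adjusted p = 0.64) and in most other alternatives. The Krt6a value is uncertain because near-identical keratin genes can share reads.

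**Figure D1:**
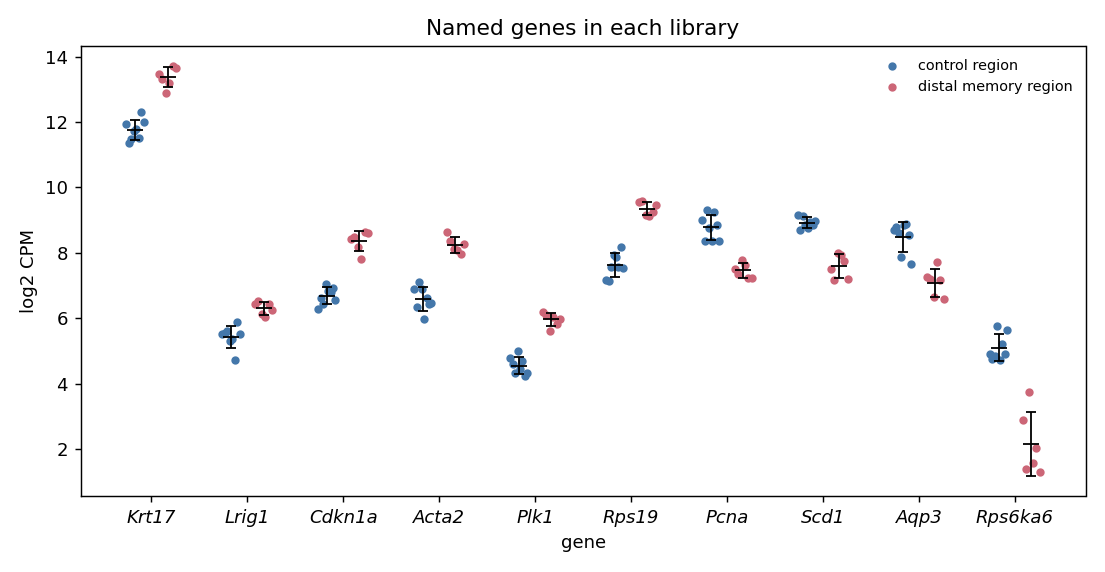
Log2 CPM (vertical axis) of 10 named genes (horizontal axis) in each of the 8 control and 6 distal libraries, with the mean and SD as bars. In the plot the distal libraries of Krt17, Cdkn1a and Rps19 all lie above the control libraries, and those of Scd1 and Rps6ka6 all lie below.

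In all, 5681 of 11757 tested genes (48.3%) passed the threshold, 2853 higher and 2828 lower in distal cells. That balance depended on the fit. It was 2206 higher and 1376 lower with counts summed per set, 3255 and 2202 with upper-quartile scaling, and 3023 and 3479 with DESeq2. The 12 largest rises among expressed genes were led by Cdsn, which encodes the corneodesmosome protein corneodesmosin. It had a log2 fold change of 3.26 ± 0.68 (SE; edgeR adjusted p = 0.00087). Ly6g6c rose by 2.51 ± 0.57 (SE) and Cst6, a cysteine protease inhibitor of the epidermis, by 2.63 ± 0.94 (SE) on the same scale. The matrix protease Mmp9 rose by 2.21 and the BMP antagonist Nbl1 by 2.32, and the serine protease Prss27 by 2.12. Cgref1, Clic3, Lynx1, Prrg2 and the DNA nuclease gene Mus81 rose by between 2.1 and 2.3. Acta1 rose by 2.57, but without distal replicate 4 its log2 fold change was 1.08 and did not pass (edgeR adjusted p = 0.15). For Nbl1, Cgref1, Clic3, Lynx1 and Prrg2 every distal library lay above every control library. Cst6 varied widely within the distal group, at 54.3 CPM ± 91.7 (SD, n = 6), and its call was lost with counts summed per set (edgeR adjusted p = 0.39). In libraries over 4000000 counts Cst6 was at -0.10 (edgeR adjusted p = 0.97). Cdsn (57.6 CPM ± 66.2, SD) and Ly6g6c (38.0 CPM ± 41.4, SD) varied widely too, and in libraries over 4000000 counts they were at 1.63 and 0.45 (edgeR adjusted p = 0.20 and 0.74).

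The largest falls included Skint1, a gene of keratinocyte and T cell interaction, with a log2 fold change of -2.83 ± 0.62 (SE; edgeR adjusted p = 0.0012). The kinase gene Rps6ka6 (chromosome X, 111388192 to 111537959) fell from 35.0 CPM ± 11.1 (SD) to 5.05 CPM ± 4.24 (SD), a log2 fold change of -2.76 ± 0.39 (SE; edgeR adjusted p = 2.8e-05). The transcription factor Maf (-2.35), the glycoprotein gene Gpnmb (-2.39), the centriole gene Cenpj (-2.33) and the desmosomal cadherin gene Dsg4 (-2.12) also fell. The remaining large falls were Zfp760 (-2.55), Zfp974 (-2.34), Phxr4 (-2.21), mt-Co3 (-2.18) and the small nucleolar RNA genes Snord80 (-2.29) and Snord78 (-2.15). The last 2 are 79 and 66 nt long. As Smart-seq2 copies polyadenylated RNA, their reads need not come from the small RNAs themselves, which was not tested. All of Skint1, Rps6ka6, Maf, Phxr4, mt-Co3, Snord80 and Snord78 were lower in every distal library than in any control library.

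The direction of the difference followed the GC content of the transcripts. Among the 20% of genes with the lowest GC content, 8 genes rose and 1242 fell, with a median log2 fold change of -0.89. Among the 20% with the highest GC content, 1565 rose and 44 fell, with a median of 1.09. GC content accounted for 51.7% of the variance of the fold changes across genes, which are not independent replicates. For each library, the deviation of log2 CPM from the gene's mean over the 14 libraries was regressed on GC content and log2 length. The slope on GC content averaged -0.46 ± 0.10 (SD, n = 8) per 10 percentage points in control libraries. In distal libraries it averaged 0.62 ± 0.29 (SD, n = 6), a difference at p = 0.00033, the smallest that the exact permutation test allows. These slopes are relative to the mean of all libraries, so slopes on both sides of 0 arise by construction. Only the difference between regions is informative, not the signs. With each library's GC and length trend removed, 2208 of 11654 genes passed, 1209 higher and 999 lower; 1594 of them had passed with the same sign before and 22 with the opposite sign. With counts summed into 4 sets, the number was 3582, of which 3510 were shared in sign with the main count. Of the genes named in this text, Cst6, Zfp760, mt-Nd6, Krt19, Plod2, Il1rap, Il1r1, Lif, H2-K1, Elovl6, Ly6a and Ddx3y lost their calls in that fit. Values for most named genes past the threshold are therefore given below with the trend in place and, in parentheses or a later sentence, with it removed.

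**Figure D2:**
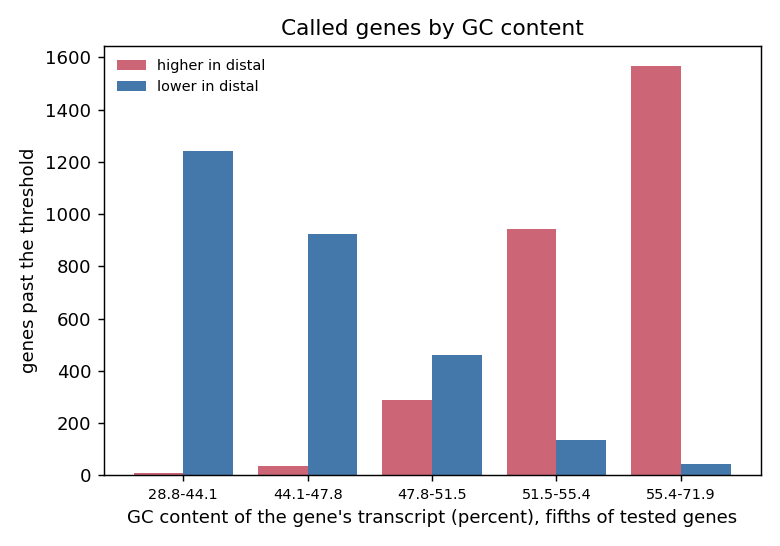
Number of genes past the threshold (vertical axis) in 5 equal groups of the tested genes by GC content in percent (horizontal axis), with genes higher and lower in distal cells as separate bars. The group of lowest GC content holds 8 higher and 1242 lower genes, and that of highest GC content 1565 higher and 44 lower.

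**Figure D3:**
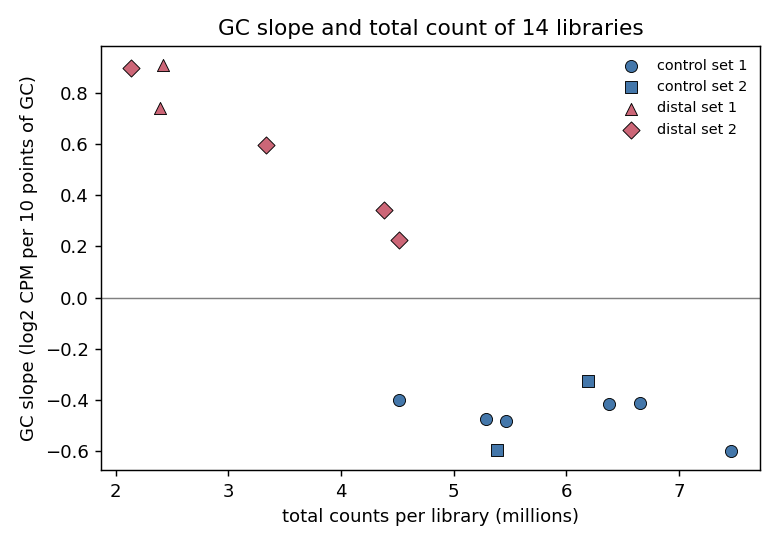
Slope on GC content, per 10 percentage points, of each library's deviation in log2 CPM from the gene mean (vertical axis). Total counts are on the horizontal axis, with one point per library and a marker for each of the 4 sets. The line at 0 is the mean of these libraries, not the absence of a GC trend. The 8 control libraries lie below it and the 6 distal libraries above it, and the totals of the regions do not overlap.

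With the trend removed, Krt17 had a log2 fold change of 0.59 ± 0.12 (SE; edgeR adjusted p = 0.0022) and Cdsn one of 2.35 (0.018). Lrig1 was then at 0.44 ± 0.16 (SE) and no longer passed (edgeR adjusted p = 0.063). Rps6ka6 was at -2.54, Maf at -2.21, Gpnmb at -2.22 and Skint1 at -2.24, and all 4 still passed. Of the other genes with large changes, calls were kept, mostly with smaller changes, by Nbl1 (1.21), Cgref1 (1.75), Clic3 (1.15), Lynx1 (1.10), Prrg2 (1.05), Ly6g6c (1.70), Cenpj (-1.67), Phxr4 (-1.58), mt-Co3 (-1.41) and Snord78 (-0.66). Calls were lost by Cst6 (1.70), Acta1 (1.66), Mmp9 (1.33), Prss27 (1.13), Mus81 (1.16), Zfp760 (-1.21), Zfp974 (-1.98), Snord80 (-0.85) and Dsg4 (-1.55), several of which stayed far from 0, so the loss does not show that GC content explains them.

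Counts of list members past the threshold are to be read against the 48.3% of all tested genes that passed. Among 28 gene lists fixed in advance, cytosolic ribosomal proteins stood out as higher in distal cells. Of 46 members, 34 rose and 3 fell, and adjusted over the list alone the counts were 35 and 3; the median log2 fold change was 1.17. Rps19 rose by 1.70 ± 0.17 (SE), Rps18 by 1.60 ± 0.15 (SE), Rpl8 by 1.54 ± 0.15 (SE) and Rpl19 by 1.51 ± 0.14 (SE). Rpl5, Rpl23 and Rpl30, named here after their values were seen, fell by 1.86, 1.25 and 1.38 on the log2 scale. The list passed camera with a preset correlation (adjusted p = 2.4e-09) but not with an estimated one (adjusted p = 0.65 with an estimated correlation). After the removal 32 members rose and 5 fell, with Rps19 (0.84), Rps18 (1.00), Rpl8 (0.54) and Rpl19 (0.83) still past the threshold. These genes share sequence with pseudogenes, and how the counting treated shared reads is not given in the sources used here.

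Cells draw energy from respiration, encoded in both genomes, and from glycolysis. Of 12 mitochondrially encoded genes 8 fell and none rose, also adjusted over the list alone, but 3 fell and none rose with counts summed per set. Log2 fold changes were -2.18 ± 0.32 (SE) for mt-Co3, -1.73 ± 0.27 (SE) for mt-Atp6, -1.78 for mt-Co2 and -0.87 for mt-Nd6. Their control means were 178.5, 43.6, 85.7 and 650 CPM. How the counting treated reads that match several places is not given, so these values are uncertain. This list passed camera (adjusted p = 0.044; adjusted p = 0.65 with an estimated correlation), but its mean difference of -0.89 from other genes turned to 0.05 with the trend removed and lost its call (adjusted p = 0.88). Then 1 member rose and 2 fell: mt-Co3 (-1.41) and mt-Atp6 (-0.85) still passed, and mt-Co2 (-1.0) and mt-Nd6 (0.01) did not. Of 46 nuclear genes of oxidative phosphorylation, 20 rose and 16 fell (20 and 17 adjusted over the list alone), but 19 and 2 with counts summed per set and 18 and 8 with the trend removed. Cox4i1 rose by 1.49 ± 0.13 (SE), Cyc1 by 1.57, Uqcrc1 by 1.37 and Atp5g1, an ATP synthase subunit gene, by 1.36. Among 21 glycolysis genes 11 rose and 4 fell, the same counts adjusted over the list alone, but 5 and 3 with the trend removed, with Gapdh at 1.43 ± 0.16 (SE), Aldoa at 1.29, Pkm at 1.16 and Eno1 at 1.13. Of 24 cholesterol synthesis genes 10 rose and 10 fell (10 and 11 adjusted over the list alone), but 9 and 3 with counts summed per set and 4 and 3 with the trend removed: Mvk (1.64) and Fdps (1.44) rose, while the epoxidase gene Sqle fell by 1.02. The nuclear genes named here kept their calls without the trend, at Cox4i1 (0.70), Cyc1 (0.44), Uqcrc1 (0.51), Atp5g1 (1.38), Gapdh (0.68), Pkm (0.46), Eno1 (0.35), Mvk (0.58), Fdps (0.99) and Sqle (-0.66), except Aldoa (0.31). Neither oxidative phosphorylation, glycolysis nor cholesterol synthesis passed camera.

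Keratinocytes move from a basal, attached state to a cornified one. Of 18 basal and hemidesmosome genes 11 rose and 5 fell, also adjusted over the list alone, but 9 and 1 with counts summed per set and 4 and 3 with the trend removed. Itgb4 and Itga3, integrins of the basal attachment, rose by 1.29 ± 0.16 (SE) and 1.19 ± 0.16 (SE), the linker gene Plec by 1.14 and Sfn by 1.22. Itgb4 stood at 0.45 and Itga3 at 0.39 with the trend removed, both still past the threshold, whereas Sfn (0.19) and Plec (0.26) were not. Differentiation and cornified envelope genes rose in 7 and fell in 3 of 22 cases (7 and 4 adjusted over the list alone; 5 and 2 with counts summed per set and 3 and 0 with the trend removed). Sbsn rose by 1.61 and the lipid transporter gene Abca12 fell by 1.29. Upper hair follicle and junctional zone genes rose in 7 and fell in 4 of 16 (8 and 5 adjusted over the list alone; 5 and 1 with counts summed per set and 3 and 2 with the trend removed). In that list Lgals7 rose by 1.23 and Aqp3, a water and glycerol channel, fell by 1.41 ± 0.22 (SE). Wound-activated and migrating keratinocyte genes rose in 11 and fell in 8 of 35, also adjusted over the list alone (10 and 4 with counts summed per set and 5 and 4 with the trend removed), with Cnn2 at 1.49, Plaur at 1.27 and Flna at 1.01. All 4 tested simple keratins rose, also adjusted over the list alone: Krt19 by 2.94, Krt7 by 2.03, Krt18 by 1.61 and Krt8 by 1.5. Krt19 had few counts, at 0.698 CPM ± 0.889 (SD) in control and 5.49 CPM ± 7.29 (SD) in distal libraries. Its call was lost with counts summed per set (edgeR adjusted p = 0.16). Of these keratins Krt18 (0.73) and Krt7 (1.21) passed with the trend removed, and Krt8 (0.60) and Krt19 (2.03) did not. Of the other genes named here Sbsn (0.85), Aqp3 (-2.09), Cnn2 (0.68) and Flna (0.42) kept their calls, and Lgals7 (0.21), Abca12 (-0.46) and Plaur (0.44) lost them. None of the 4 testable lists in this paragraph passed camera, and the simple keratin list was too short for that test.

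**Figure D4:**
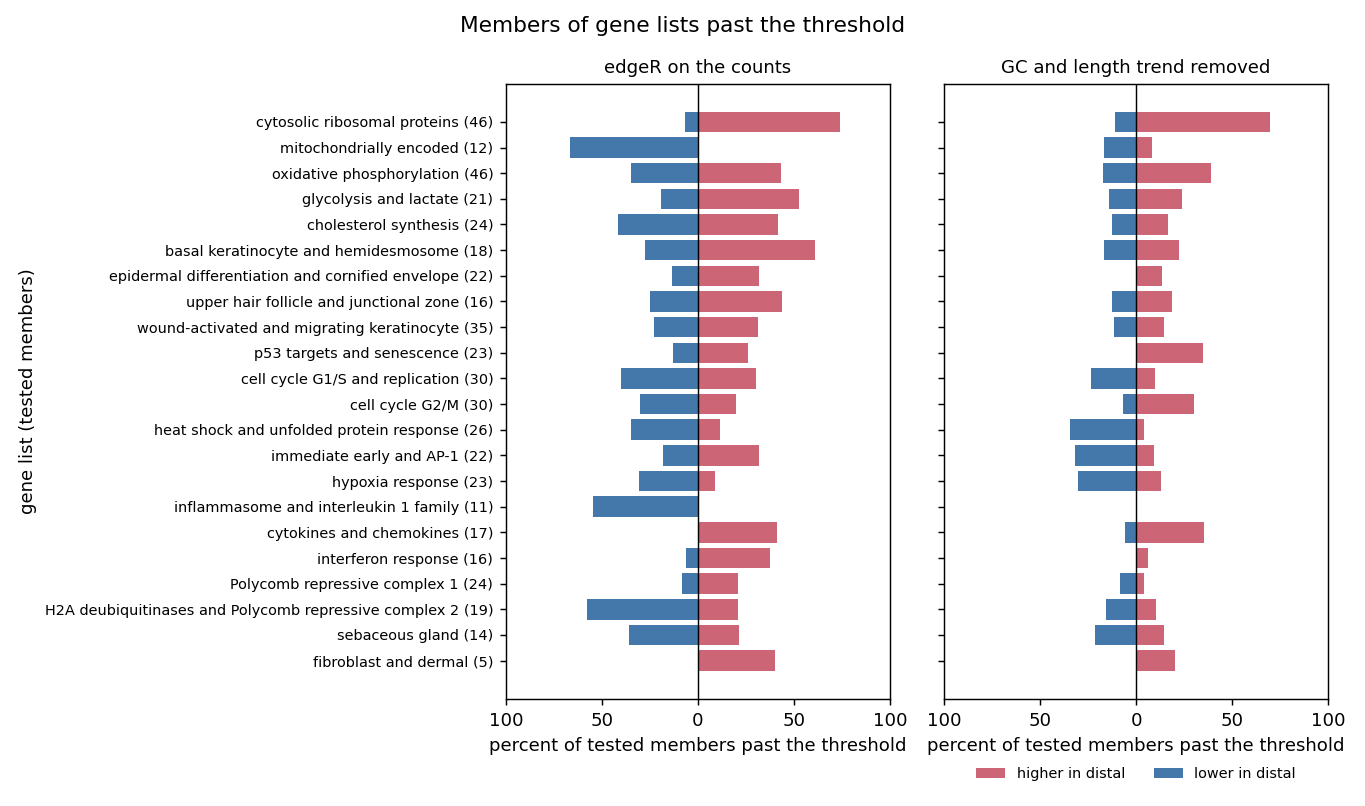
Percent of tested members past the threshold (horizontal axis) for 22 described gene lists (vertical axis, tested members in parentheses), to the right for members higher and to the left for members lower in distal cells. The left panel has the counts as deposited and the right panel the fit with the GC and length trend removed, in which the mitochondrially encoded list goes from 8 lower members to 2.

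Growth arrest and DNA damage responses act in part through targets of p53. The p53 and senescence list had 6 higher and 3 lower members of 23, also adjusted over the list alone, and the other 14 did not pass. That is a smaller share past the threshold than the 48.3% of all tested genes. The cell cycle inhibitor gene Cdkn1a (chromosome 17, 29090976 to 29100727) rose from 104 CPM ± 18.7 (SD, n = 8) to 332 CPM ± 64.3 (SD, n = 6), a log2 fold change of 1.67 ± 0.16 (SE; edgeR adjusted p = 1.6e-06). Aen rose by 1.71, Phlda3 by 1.55 and the death effector gene Bax by 1.46. After the removal of the trend 8 members rose and none fell, with Cdkn1a at 1.01 ± 0.13 (SE) and Aen (0.89), Phlda3 (0.53) and Bax (0.40) also past the threshold. G1/S and replication genes rose in 9 and fell in 12 of 30 (9 and 13 adjusted over the list alone), but 3 and 7 with the trend removed. Pola1 (-1.57), Pcna (-1.36) and Rrm2 (-1.04) fell and the helicase gene Mcm7 rose by 0.85; without the trend they were at Pola1 (-0.69), Pcna (-0.60), Rrm2 (-0.67) and Mcm7 (0.74), all past the threshold. G2/M genes rose in 6 and fell in 9 of 30 (7 and 9 adjusted over the list alone), and with the trend removed 9 rose and 2 fell. Cdca3 rose by 1.5, Plk1 by 1.42, Ube2c by 1.26 and Cenpa by 1.05, and with the trend removed Cdca3 (0.80), Plk1 (0.56), Ube2c (0.77) and Cenpa (0.64) still passed. These lists did not pass camera in either fit.

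Stress response lists changed their standing with the GC trend. Of 26 heat shock and unfolded protein genes 3 rose and 9 fell (4 and 9 adjusted over the list alone). Hspb1 rose by 1.38, while Hsp90b1 (-1.33), Dnaja1 (-1.25) and the mitochondrial chaperone gene Hspd1 (-1.0 ± 0.13, SE) fell. Of 22 immediate early and AP-1 genes 7 rose and 4 fell, also adjusted over the list alone, with Myc at 1.16, Zfp36 at 0.86, Fosl2 at -1.04 and Fos at -1.16. Hypoxia genes rose in 2 and fell in 7 of 23, also adjusted over the list alone: Angptl4 rose by 1.64, and Car12 (-1.57), Hif1a (-1.25) and Plod2 (-0.99) fell. With the trend removed, 1 rose and 9 fell of the heat shock list, 2 and 7 of the immediate early list, and 3 and 7 of the hypoxia list. Calls were lost by Hspb1 (0.25), Zfp36 (0.30) and Plod2 (-0.18) and kept by Hsp90b1 (-0.62), Dnaja1 (-0.57), Hspd1 (-1.28), Myc (0.41), Fosl2 (-1.30), Fos (-1.99), Angptl4 (0.85), Car12 (-1.27) and Hif1a (-0.42). These lists then passed camera at adjusted p = 0.0035, 0.0091 and 0.03, and each had adjusted p = 0.10 with an estimated correlation; none had passed with the trend in place.

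Inflammatory genes gave no single direction. Of 11 inflammasome and interleukin 1 genes none rose and 6 fell, also adjusted over the list alone (0 and 3 with counts summed per set). Among the 6 were Casp4 (-2.59), Nlrp10 (-1.17), Il1rap (-0.88) and Il1r1 (-0.68). Casp4 had few counts, at 5.26 CPM ± 3.58 (SD) in control and 0.855 CPM ± 0.707 (SD) in distal libraries. None of the 11 passed with the trend removed, with Casp4 (-1.78), Nlrp10 (-0.32), Il1rap (0.00) and Il1r1 (0.13). Cytokine and chemokine genes rose in 7 of 17 with no fall, also adjusted over the list alone, with Csf3 at 2.63, Tnf at 1.19 ± 0.25 (SE), Lif at 1.07 and Cxcl3 at 1.06 ± 0.29 (SE). Csf3 had few counts, at 0.94 CPM ± 1.01 (SD) in control and 6.0 CPM ± 5.5 (SD) in distal libraries. With the trend removed, 6 rose and 1 fell and the list passed camera (adjusted p = 0.03; adjusted p = 0.49 with an estimated correlation). Of the named cytokines Tnf (0.89) and Cxcl3 (1.96) then passed and Csf3 (1.75) and Lif (0.81) did not. Interferon response genes rose in 6 and fell in 1 of 16, also adjusted over the list alone (3 and 0 with counts summed per set). The antigen presentation genes H2-D1 and H2-K1 rose by 1.18 and 0.72, Ifi35 by 1.54 and Ifi27 by 1.82. Ifi27 had few counts, at 1.71 CPM ± 1.07 (SD) in control and 6.12 CPM ± 3.76 (SD) in distal libraries. H2-D1 (0.74) was the only member to pass with the trend removed, and H2-K1 (-0.14), Ifi35 (0.73) and Ifi27 (1.45) lost their calls.

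Polycomb complexes repress genes by modifying histones H2A and H3. Of 24 genes of Polycomb repressive complex 1, 5 rose and 2 fell (3 and 2 adjusted over the list alone). With counts summed per set it was 2 and 2, and with the trend removed 1 and 2. Phc2 rose by 1.66 and Scmh1 by 1.03, and Pcgf6 fell by 0.97. The E3 ligase gene Rnf2 (chromosome 1, 151458004 to 151500955) fell from 84.8 CPM ± 19.1 (SD) to 44.8 CPM ± 14.9 (SD), a log2 fold change of -0.92 ± 0.21 (SE; edgeR adjusted p = 0.0016). Ring1 had a log2 fold change of 0.60 ± 0.39 (SE) and did not pass (edgeR adjusted p = 0.21), nor did it with the trend removed (-0.43, edgeR adjusted p = 0.53). Rnf2 was at -0.34 ± 0.18 (SE) without the GC trend and no longer passed (edgeR adjusted p = 0.22). Scmh1 (0.71) and Pcgf6 (-0.33) also lost their calls, and Phc2 (0.58) kept its own. Of 19 genes of H2A deubiquitinases and Polycomb repressive complex 2, 4 rose and 11 fell, also adjusted over the list alone. Jarid2 fell by 1.86, Asxl2 by 1.5 and Rbbp7 by 1.0, while Epop rose by 1.58; with the trend removed 2 rose and 3 fell, and Jarid2 (-1.94), Asxl2 (-0.63), Rbbp7 (-0.51) and Epop (0.70) still passed. Neither list passed camera in either fit.

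Few markers of other cell types had enough counts to be tested. Of 24 fibroblast and dermal genes 5 could be tested, and Acta2, an actin of contractile cells, rose from 99.1 CPM ± 24.8 (SD) to 306 CPM ± 54.5 (SD), a log2 fold change of 1.63 ± 0.17 (SE; edgeR adjusted p = 2.5e-06). Gsn rose by 0.93, whereas Col1a2 (24.1 CPM ± 58.3, SD, and 14.1 CPM ± 29.5, SD) and Prrx1 did not pass. Col1a2 was at 7.40 log2 CPM in control replicate 1 and 6.22 in distal replicate 3, and at 3.27 or less in every other library. Prrx1 was highest of each region in the same libraries, at 5.14 and 3.63 log2 CPM. Acta2 kept its value without the trend (1.65) and Gsn, at 0.02, lost its call. Of 3 tested endothelial genes Egfl7 rose by 1.34, and Kdr (0.36) and Flt1 (0.16) did not pass; Egfl7 lost its call without the trend (0.33). The single tested melanocyte gene Mitf (-0.61) and the single tested immune gene Cd68 (0.24) did not pass; the other listed genes of both kinds had too few counts to be tested. Sebaceous gland genes rose in 3 and fell in 5 of 14, also adjusted over the list alone (2 and 3 with the trend removed): the desaturase gene Scd1 fell by 1.30 ± 0.16 (SE) and the elongase gene Elovl6 by 0.91, while Plin2 rose by 1.02 and Fasn by 0.66. Scd1 (-2.19), Elovl6 (-0.43) and Plin2 (0.74) kept their calls once the trend was removed, and Fasn went to the other direction, at -0.38 (edgeR adjusted p = 0.014).

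Sets of the same region were compared to see how far they differ without a change of region. Between control set 2 and control set 1 no gene passed in edgeR, with 969 genes at an unadjusted p under 0.05 where 588 were expected, and DESeq2 called 45. The leading genes were Slc18a2, with a log2 fold change of 1.18 ± 0.22 (SE), and the cornified envelope genes Sprr1a (3.51 ± 0.66, SE) and Cnfn (4.27 ± 0.87, SE), each at edgeR adjusted p = 0.29. Between distal set 2 and distal set 1 no gene passed in edgeR, with 921 at an unadjusted p under 0.05, and DESeq2 called 31. The leading gene there was Sprr1b, at -1.43 ± 0.24 (SE; edgeR adjusted p = 0.24). These genes are named by their p and were chosen after their values were seen.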

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

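The tests of GC content as the whole cause, of the GC slope against depth and region, and of ribosomal genes against matched lists were chosen only after the results were seen. Among 262 groups of values, 4 had a library farther from the others than Dixon's 95% critical value allows, where chance alone gives about 13. Control replicate 8 had Cst6 at 5.80 log2 CPM against 0.63 to 1.74 in the other control libraries (gap ratio 0.787). Control replicate 7 had Plaur at 6.72 against 5.83 to 6.22 (gap ratio 0.561). Control replicate 5 had Mitf at 3.96 against 4.97 to 5.53 (gap ratio 0.645). Distal replicate 3, the deepest distal library, had Sfn at 10.3 against 10.6 to 10.8 (gap ratio 0.638).

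The number of genes between regions was the first pattern weighed. Of 100 splits of the 14 libraries into 8 and 6, 1 gave as many genes, the real one, with 5681 against at most 1955 in the others, so chance in how single libraries were grouped is excluded. That treats libraries as exchangeable. With sets kept whole and 2 sets on each side only 2 other groupings exist, which gave 0 genes each. They are too few to exclude chance between sets. With every library thinned to the smallest total 4936 genes passed against at most 1869 in other splits, which argues against fewer counts as such. With the GC and length trend removed 2208 genes passed against at most 227 in other splits, so the trend as fitted does not account for those calls. The other splits mix the regions, and most called 0 genes before any removal. They cannot show how many calls an incomplete removal leaves, so GC content and length as the whole cause are not excluded. Also open is any step that differed between the regions' libraries, since the sets are nested in the regions. Only 26 genes passed when the removal was joined to libraries over 4000000 counts (2 distal). The regional difference that the design names stays open too, as untested.

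The GC trend of the fold changes was the second. Within the 6 distal libraries the GC slope, relative to the mean of all libraries, was higher where fewer counts were obtained. Pearson's r was -0.977 (exact permutation p = 0.011, adjusted p = 0.022 over 2 relations) and Spearman's rho -0.829 (exact permutation p = 0.058). Without the 2 libraries farthest from the median, r was -0.878. Within the 8 control libraries r was -0.186 (exact permutation p = 0.65) and rho -0.214 (exact permutation p = 0.62); without the 2 farthest, r was 0.698. A library-making step that varies with yield is a candidate cause in the distal libraries. The deepest distal and the shallowest control library, with nearly equal totals, still differed by 0.625 in slope, but a single pair decides nothing and the totals of the regions do not overlap, so a difference between regions cannot be told apart from depth.

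The higher counts of cytosolic ribosomal protein genes were the third. Their median log2 fold change was 1.17. The middle 95% of 10000 random lists matched on GC content, length and expression ran from -0.18 to 0.55. The median lay above that range, with GC content and length taken as medians over annotated transcripts. Random members were drawn independently, whereas members of the ribosomal list had an estimated correlation of 0.49. The range is therefore too narrow for such a list, and those properties are not excluded. The 52 tested pseudogenes with an Rpl or Rps symbol and -ps had a median of 0.29 (21 rose and 9 fell). Their summed counts were 365 CPM in control and 474 CPM in distal libraries against 19290 and 30213 CPM in the genes. Those pseudogenes thus held too few counts, and did not lose them, to supply the rise. Ribosomal pseudogenes under other symbols were not counted and stay open as a source. Other effects of shared reads stay open too, as their treatment is not given. The list test itself is weak: 36 of 100 splits of the libraries gave at least the 2 lists of the real split, with up to 7 in another split, so chance is not excluded for the number of lists. A regional difference may underlie the ribosomal pattern, but this remains a hypothesis, since depth and region coincide.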

How the results depend on the processing

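The GC, length, depth cut and total count alternatives were chosen only after the results were seen; the others were planned. The 5681 genes between regions became 3581 with genes detected as a covariate, 3582 with counts summed per set, 2267 without control set 1, 2208 with GC and length removed, 311 with that removal on summed counts, 1243 in libraries over 4000000 counts, 26 there with GC and length removed, and 952 with total count as a covariate. The other fits with all libraries, and those without another set, lay between 4070 and 6502. Leaving out 1 library gave 4911 to 5842. The cause of these shifts was not tested, except that fewer libraries or sets enter several fits. The 2 lists became 5 without a filter on low counts, 4 with the set as a correlated block, 22 with fry, 0 with an estimated correlation, 1 without control set 2, 5 with GC and length removed (0 with an estimated correlation), and 4 in libraries over 4000000 counts with that removal. Leaving out 1 library gave 1 to 2 lists, with 1 without control replicate 5 or distal replicate 1. Replicate numbers do not pair the libraries: same-numbered ones correlated at -0.017 to 0.110, and only number 3 matched its own number best. With the replicate number as a block 5442 genes and 1 list passed. Set number as a block gave 5659 genes, and 4712 on counts summed per set. For sets of a region the 0 genes became 113 (control) and 81 (distal) without a filter on low counts, and 45 and 31 with DESeq2. Leaving out 1 library gave 0 to 2 genes between control sets, the 2 without control replicate 7.

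Genes detected differed by -615 without control set 1 and -967 without distal set 2, where the exact permutation test no longer passed, and by 160 after thinning, in the other direction. The mitochondrial percent differed by -1.18 without control set 2 and -1.13 without distal set 1, both no longer past the threshold. The percent in the 50 largest genes, never past it, went to -1.77 without control set 1 and -0.614 without distal set 2. For named genes and lists, the rescalings gave no change of direction. With GC and length removed, 80 of 131 kept their direction and side of the threshold, 35 lost their call and 3 gained one. With total count as a covariate 56 of 125 lost their call, on summed counts with GC and length removed 88 of 125, in libraries over 4000000 counts 45 of 131, and there with GC and length removed 103 of 131, so most named calls do not hold under the joined removals. With GC and length removed alone these turned: mt-Nd6 0.01, Il1rap 0.00, Il1r1 0.13, H2-K1 -0.14, Fasn -0.38, Cd68 -0.40, Ring1 -0.43, Krt6a -0.33, Ddx3y 0.37, Uty 0.03, Kdm5d 0.05, the immediate early list -0.43 and the mitochondrially encoded list 0.05 (both the same with an estimated correlation). On summed counts with that removal these turned: mt-Nd6 0.24, Plod2 0.04, Il1rap 0.16, Il1r1 0.13, H2-K1 -0.26, Fasn -0.39, Col1a2 0.30, Cd68 -0.33, Ring1 -0.14, Krt6a -0.22, Xist 0.14, Ddx3y 0.70, Uty 0.08 and Kdm5d 0.12. In libraries over 4000000 counts Cst6 was at -0.10, Col1a2 at 0.68 and Cd68 at -0.12. There with GC and length removed these turned: Cst6 -0.81, Ly6g6c -0.13, mt-Nd6 0.17, Il1rap 0.28, H2-K1 -0.21, Fasn -0.41, Prrx1 0.19, Col1a2 1.11, Cd68 -0.58, Krt6a -0.38, Ddx3y 0.22, Uty 0.15, the immediate early list -0.39 and the mitochondrially encoded list 0.26. With total count as a covariate Col1a2 was at 0.84, Cd68 at -0.64, Krt6a at -0.24 and Ddx3y at 0.15. Col1a2, never past the threshold, was also positive with genes detected as a covariate (0.70), limma-voom (0.40; 0.43 with the set as a block), set number as a block (0.04; 0.46 on summed counts) and without control set 1 (3.96). Flt1 was at -0.13 with the replicate block and -0.54 without distal set 2. The cause was not tested. Depth limits genes with few counts most, and only 2 distal libraries exceed 4000000 counts.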

Other observations

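The comparison below was chosen after the results were seen. Across 4 fits (all libraries, GC and length removed, counts summed per set, and libraries over 4000000 counts), 699 genes passed in the same direction, 517 higher and 182 lower in distal cells. Among the lower genes, the desaturase gene Scd1 fell from 486 CPM ± 58.7 (SD, n = 8) to 198 CPM ± 48.6 (SD, n = 6), its relative Scd2 from 1554 CPM ± 283 (SD) to 547 CPM ± 78.8 (SD), and Aqp3 from 374 CPM ± 102 (SD) to 141 CPM ± 42.3 (SD). Tfap2a, a transcription factor of epidermal development, fell from 136 CPM ± 25.1 (SD) to 51.7 CPM ± 10.4 (SD), and the histone methyltransferase gene Setd1b from 39.3 CPM ± 8.97 (SD) to 17.1 CPM ± 2.44 (SD). With the trend removed the log2 fold changes were -2.19 for Scd1, -2.19 for Tfap2a, -2.09 for Aqp3 and -2.05 for Setd1b. Among the higher genes were the splicing genes Snrpf, from 15.7 CPM ± 3.18 (SD) to 58.1 CPM ± 8.18 (SD), and Sf3b5, from 35.7 CPM ± 10.7 (SD) to 91.8 CPM ± 21.7 (SD). The translation factor gene Eef1a1 rose from 1329 CPM ± 335 (SD) to 3119 CPM ± 254 (SD), and the translation regulator gene Eif4ebp1 from 49.1 CPM ± 11.5 (SD) to 143 CPM ± 26.5 (SD). These genes were picked by subject after their values were seen, and genes with larger changes were passed over. The fits share libraries, so they are not independent.

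With the GC trend removed, 9 of 26 heat shock and 7 of 22 immediate early genes fell and most members did not pass; each list had adjusted p = 0.10 in camera with an estimated correlation. The immediate early list's mean difference from other genes was 0.23 with the trend in place and -0.43 with it removed. Over-correction of GC-rich genes was examined as a cause of the falls, in a test chosen after the results were seen. The median log2 fold change of the 2 lists joined was -0.40. The middle 95% of 10000 random lists matched on GC content, length and expression ran from -0.24 to 0.20. Those lists come from the same fit, which centres genes of a given GC content near 0, and their members were drawn independently. The test therefore cannot show a wrong correction of the listed genes, whose GC content was a median over transcripts. Taken alone, the immediate early list lay below its range (-0.49, with a lower end of -0.28). The heat shock list was at the edge of its own (-0.345, with a lower end of -0.340). Over-correction stays possible for both lists.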
